A study of Mus musculus with 8 samples.

How the data were processed

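RNA came from punches of 500 µm diameter taken from the middle of the striatum in coronal slices 300 µm thick at postnatal day 0, per the labels and the series' design text. The mice were 3 wild type, 1 heterozygote and 4 Ctip2 null animals, each array holding RNA of 1 animal, so that p values measure the spread between animals. The deposited values are log2 expression values per probe set of an Affymetrix array, made by the authors with RMA in Bioconductor, per the series' design text. RMA corrects background, normalizes probe intensities across arrays by quantiles and summarises each probe set by median polish. Its version, which arrays were normalized together and any filter are not given in the sources used here. After that step the SD of log2 values still differed between arrays, from 1.84 to 2.06, so an array-wide difference in signal spread remains in the values and can move many probe sets together. The mice were of strain BALB/c, per the labels.

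The values were used as deposited. Control probe sets were left out. Of 45037 probe sets, 34945 carry 1 gene symbol in the array's annotation, 932 several and 9160 none; 204 of those with 1 symbol were not found in the reference gene table (assembly GRCm38.p6, used here only for names and for which genes neighbour each other; no chromosome positions are printed, because the array file names no build). A gene was represented by its probe set, with 1 symbol, of highest mean over the 7 wild type and null arrays, which gave 18193 genes. Probe sets of 1 gene, Rcn1, passed the threshold in both directions. Of the named genes that passed, Bnc2, Arpp21, Six3, Kcnip1, Bach2, Msi2, Slc1a2, Nrp1, Cdh4, Cdh10, Pcdh9, Xiap, Peg3 and Dcc have at least 1 other probe set of opposite sign, and Plagl1, Reln, Cacna2d2, Gusb and Usp29 have only such others; none of these passed.

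Wild type and null arrays were compared with limma (version 3.58.1 in R 4.3.3), using lmFit and eBayes on the 7 arrays with no covariate and Benjamini-Hochberg adjustment over all probe sets or all genes, with a threshold of 0.05. Errors beside means are SDs. On simulated values for 45037 probe sets with the same group sizes, 82 of 100 probe sets changed by 1 log2 unit and 100 of 100 changed by 1.5 were called, with 12 false among 194 calls. The simulated noise was independent between probe sets and held no array-wide difference, unlike these arrays, so the rates may not hold for them. The main tests left out the heterozygote. Only the alternatives named below and the correlation of Ttr with other genes included this array. Its value on each called gene was expressed as a position between the group means, and since the wild type arrays enter both differences, simulated wild type arrays and each wild type array left out in turn were placed in the same way. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

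Before the data were examined, 33 gene lists for striatal cell types, compartments, signalling, guidance, other tissues and controls were written from general knowledge, together with the alternatives below. Lists share members: 14 genes of the striatal transcription factor list and 10 of the olfactory bulb list are on another list too. Each list was tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry, which asks whether a list's genes move on balance in 1 direction without comparing them with other genes. Listed genes without a probe set of 1 symbol, such as Adora2a, were not analysed here.

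The genes named were fixed by a rule: Bcl11b; the 12 largest rises and 12 largest falls among genes past the threshold whose wild type and null arrays do not overlap, leaving out predicted models and clone names; and from each list the 2 members of largest absolute change and, where 3 or more passed, up to 4 of those. Genes named after their values were seen are marked as such. Alternatives to the test were the SAM d statistic, an intensity trend with a robust prior, array weights and other thresholds. Alternatives to the values were a filter on dim probe sets, arrays centred on their median, quantile normalization, and other ways to represent a gene. Alternatives to the samples were each array left out in turn, the heterozygote as a control or as a group of its own, the replicate number as a block and the omission of the chromosome of Bcl11b and the sex chromosomes. After the data were seen, the SD of each array, its Xist value, and the omission of wild type 1 and null 2 were added. The study's own selection used SAM scores beyond 2 in either direction and kept 153 genes, per the series' design text. That list was not analysed here. The score computed here passed 2 on 10347 probe sets, so the cut is not the same as the study's.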

Results

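Gene expression in the striatum of newborn mice was measured on 8 Affymetrix arrays, each hybridised with RNA from a different mouse. The arrays comprised 3 wild type, 1 heterozygote and 4 Ctip2 null animals at postnatal day 0. Ctip2, listed under its current symbol Bcl11b, encodes a zinc finger transcription factor of medium spiny neurons, the projection neurons that make up most of the striatum. The comparison asks which striatal genes differ when this factor is missing. The values covered 45037 probe sets and, with 1 probe set per gene, 18193 genes. Array medians lay between 6.21 and 6.35 on the log2 scale, and the number of arrays limits the precision of every value.

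Bcl11b itself was lower in the null arrays on each of its 4 probe sets, and wild type and null arrays did not overlap on any of them. Its brightest probe set, which represents the gene, read 12.29 ± 0.25 (SD, n = 3) in wild type and 11.18 ± 0.20 (SD, n = 4) in null striatum, 2.16-fold lower (adjusted p = 0.0091). The other probe sets were 2.29-fold, 2.63-fold and 3.16-fold lower (adjusted p = 0.0093, 0.0011 and 0.0152). The heterozygote array stood at the wild type level, with 12.43 on the brightest probe set and 11.33 against a wild type mean of 11.40 on the one of smallest p. Signal remained in every null animal, and which part of the gene was deleted is not given in the sources used here, so a probe set outside that part would not test the labels. The fit without wild type 1 and null 2, the arrays of highest Ttr, was chosen after seeing the data and has fewer animals in each group. In it the difference on the brightest probe set was -1.01. Adjusted over genes instead of probe sets, the p for Bcl11b was 0.0571 in that fit and 0.0069 in the main fit.

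**Figure D1:**
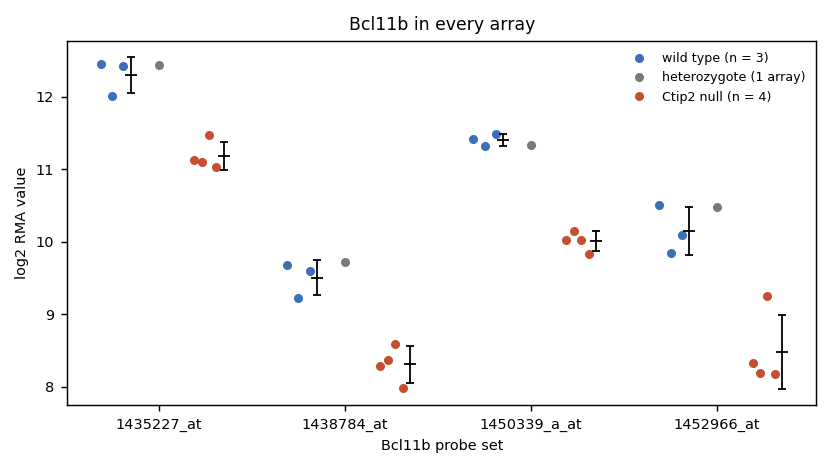
Log2 RMA value of the 4 Bcl11b probe sets in each array, with wild type in blue (n = 3), the heterozygote in grey (1 array) and Ctip2 null in red (n = 4); horizontal ticks and bars are group means and SD. Every null array lies below every wild type array on each probe set, and the heterozygote reads 12.43 on the brightest probe set against a wild type mean of 12.29.

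Among genes past the threshold, more were higher than lower in the null striatum. SAM scores beyond 2 in either direction, a looser cut, gave the reverse, with 2026 genes higher and 2341 lower. At a limma adjusted p under 0.05, 521 genes were higher and 143 lower, of which 290 and 52 differed at least 2-fold. Over probe sets the counts were 840 higher and 204 lower, so that 80.5% of the called probe sets were higher, and 8836 probe sets passed an unadjusted p of 0.05. Wild type and null arrays did not overlap on 16.5% of probe sets, where chance gives 5.71%, with wild type above null on 3984 and below on 3469, and the median difference over all probe sets was -0.08. Quantile normalization of the deposited values gave 518 higher and 277 lower genes, a higher share of 65.2% against 78.5%. The arrays also differed in how widely their log2 values spread, with an SD of 1.97, 1.84 and 1.87 in wild type 1 to 3, 2.06 in the heterozygote and 1.96, 2.03, 2.05 and 1.90 in null 1 to 4. The first principal component, with 54.1% of the variance, placed wild type 1 to 3 at -12.5, -70.9 and -55.0, the heterozygote at 46.0 and null 1 to 4 at 10.3, 36.3, 62.8 and -17.0. With each array's SD as a covariate, chosen after seeing the data, 133 genes were higher and 81 lower, and with the heterozygote counted among the controls 74 were higher and 78 lower. Single arrays moved the gene counts by over 1.5 times: without wild type 1, 2 or 3 there were 1030, 189 or 150 higher and 253, 67 or 65 lower genes, without null 1, 2 or 3 there were 248, 195 or 303 higher and 66, 58 or 91 lower, and without null 4 there were 987 higher genes. Without wild type 1 and null 2 together, 291 were higher and 49 lower.

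The largest rises were in genes of several kinds. Bnc2, a zinc finger protein, rose 16.8-fold, from 5.92 ± 0.51 (SD, n = 3) to 9.99 ± 0.35 (SD, n = 4), with an adjusted p of 9.08e-05. Fign, a microtubule-severing ATPase, rose 9.27-fold, Dlk1, a Notch-pathway protein from an imprinted locus, 7.47-fold, and Nts, the precursor of the neuropeptide neurotensin, 6.10-fold. Plagl1, an imprinted zinc finger gene, rose 6.03-fold on 1 of its 3 probe sets, the other 2 differing the other way without passing, and the netrin receptor gene Unc5d rose 5.30-fold. The neurofilament genes Nefl and Nefm rose 6.03-fold and 4.96-fold, and Elavl4, which encodes a neuronal RNA-binding protein, rose 5.22-fold. Hspa1b, an inducible heat shock protein gene, Lonrf3 and Asb4 rose 5.25-fold, 5.17-fold and 5.02-fold. Wild type means of Fign, Hspa1b, Lonrf3, Unc5d, Bnc2 and Asb4 ranged from 4.75 to 6.02, below the array medians. No detection limit was set, so folds that start from such low values may be imprecise. The heterozygote lay past the midpoint between the wild type and null means on 4 of these 12 genes, Plagl1, Hspa1b, Elavl4 and Asb4, and within 0.25 of that distance from the wild type mean on 5 of them, Bnc2, Fign, Dlk1, Nts and Unc5d. With the heterozygote among the controls, Plagl1 and Asb4 had adjusted p values of 0.0870 and 0.0921. Asb4 also had 0.0610 without wild type 2, 0.0629 without wild type 3, 0.0767 without the pair of arrays highest in Ttr and 0.135 with the spread covariate, and Elavl4 had 0.0604 with that covariate.

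The largest falls were also in genes of several kinds. Itpka, an inositol trisphosphate kinase of dendritic spines, fell 9.97-fold, with an adjusted p of 3.08e-05. Nexn, an actin-binding protein, fell 9.20-fold, from 9.86 ± 0.48 (SD, n = 3) to 6.66 ± 0.34 (SD, n = 4), and Thy1, a neuronal surface glycoprotein, fell 4.61-fold. Gpr6, a receptor of indirect pathway neurons, fell 4.48-fold, the small GTPase gene Rasl11b 4.38-fold and the myosin motor gene Myo5b 4.05-fold. Dbp, a clock-controlled transcription factor, fell 3.85-fold, Lamp5 3.67-fold, Arpp21, a cyclic AMP-regulated phosphoprotein of medium spiny neurons, 3.63-fold, and Arhgdib 3.59-fold. Cracdl and the semaphorin receptor gene Plxnd1 fell 3.56-fold and 3.45-fold. Null means of Itpka, Gpr6, Myo5b and Lamp5 ranged from 4.69 to 5.91, below the array medians, so these folds may be imprecise too. The heterozygote stood within 0.25 of the distance from the wild type mean on 8 of these 12 genes and past the midpoint on 0. Gpr6, with a wild type SD of 1.22, was the least stable: its adjusted p was 0.0577 without wild type 2, 0.0797, 0.109 and 0.0767 without null 1, 2 or 3, 0.0747 with arrays centred on their median, 0.0517 with the heterozygote among the controls and 0.106 with the spread covariate. Arpp21 had 0.0669 without wild type 2, 0.0577 without wild type 3 and 0.143 with that covariate.

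**Figure D2:**
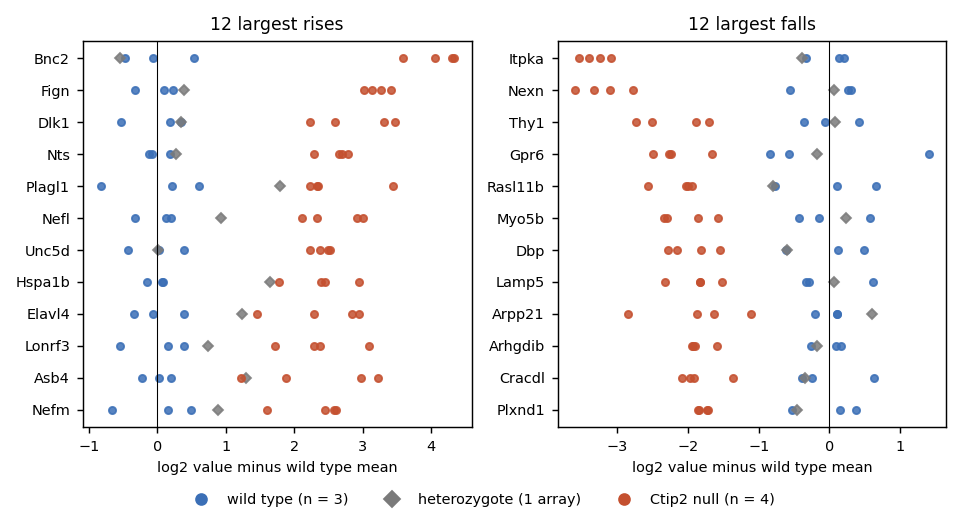
Log2 value of each array minus the wild type mean for the 12 genes with the largest rise (left) and the 12 with the largest fall (right), with wild type arrays in blue (n = 3), the heterozygote as a grey diamond (1 array) and null arrays in red (n = 4). Bnc2 stands 4.07 higher and Itpka -3.32 on the log2 scale, and the heterozygote is near wild type for Bnc2 and closer to null for Plagl1.

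Many genes of medium spiny neuron signalling fell. Of 30 measured members of that list, 13 were lower, 0 were higher and 17 did not pass. Adjusted over the list alone, 17 were lower and 1 higher. Arpp21, named with the largest falls, was among them. Kcnip2, a potassium channel subunit gene, fell 3.10-fold, from 9.47 ± 0.26 (SD, n = 3) to 7.83 ± 0.21 (SD, n = 4). Gng7, a G protein subunit that couples dopamine and adenosine receptors to cyclic AMP, fell 3.10-fold, and Ngef, which encodes a protein acting downstream of Eph receptors, fell 2.87-fold. Members named here after their values were seen include Ppp1r1b, the phosphoprotein DARPP-32, 2.46-fold lower, Pde10a, the striatal phosphodiesterase, 2.06-fold lower, and Drd1, the D1 dopamine receptor, 1.91-fold lower. Also chosen after their values were seen, Drd2, the D2 receptor, differed by -0.21 (adjusted p = 0.410) and Penk, which encodes enkephalin, by 0.21 (adjusted p = 0.661). Camera gave the list a lower level, with a mean log2 difference of -0.55 and an adjusted p of 2.90e-07, and an adjusted p of 0.0986 with an estimated correlation. Counting the heterozygote among the controls left 12 members lower, the signal spread covariate 7, and omission of the pair of arrays highest in Ttr 9. Drd1 lost its call in all 3 of these settings and Ppp1r1b in the latter 2, and both did with single arrays left out, Ppp1r1b with 0.0701 without wild type 2 and 0.0638 without null 2, and Drd1 with 0.111 without wild type 2 and 0.0642, 0.117 and 0.0814 without null 1, 2 or 3.

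Some transcription factors of striatal projection neurons rose in null striatum, and most did not pass. On the list of striatal projection neuron transcription factors 5 of 22 rose, 0 fell and 17 did not pass, with 10 higher and 1 lower adjusted over the list alone. Six3 rose 2.58-fold, from 7.71 ± 0.18 (SD, n = 3) to 9.08 ± 0.12 (SD, n = 4), Zfp503 2.47-fold, Zfp521 2.19-fold and Tshz1 2.13-fold. Of genes chosen after their values were seen, Foxp1 differed by -0.22 (adjusted p = 0.414), Foxp2 by 0.63 (adjusted p = 0.0898) and Meis2 by 0.57 (adjusted p = 0.0547). The camera adjusted p was 1.98e-04, and 0.0742 with an estimated correlation. The heterozygote read 7.80 on Six3, near wild type, and 10.98 on Zfp521 and 8.77 on Tshz1, past the null means of 10.85 and 8.56. With it among the controls 2 members were higher, and 3 were with the spread covariate, without wild type 3 or without null 1. Without wild type 1 or null 3 there was 1 lower member. Tshz1 lost its call without wild type 2 (0.0751), wild type 3 (0.0882) or null 1 (0.0632), while Foxp2 (0.0142) and Meis2 (0.0273) were called without wild type 1.

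Some genes of GABAergic identity and of the dorsal lateral ganglionic eminence (LGE), the source of olfactory bulb interneurons, also rose. On the list of olfactory bulb interneuron and dorsal LGE genes 6 of 14 rose, 0 fell and 8 did not pass (8 higher and 0 lower adjusted over the list alone), and on the list of GABA synthesis, transport and Dlx genes 6 of 18 rose, 0 fell and 12 did not pass (10 and 0). The homeobox genes Dlx1 and Dlx2, members of both, rose 3.53-fold and 2.84-fold, Dlx1 from 7.49 ± 0.32 (SD, n = 3) to 9.31 ± 0.17 (SD, n = 4). Gad1, which encodes a GABA-synthesising enzyme, rose 2.67-fold, Calb2, the interneuron calcium-binding protein calretinin, 2.86-fold, Th, tyrosine hydroxylase, 2.63-fold and the GABA receptor subunit gene Gabrg3 1.78-fold. Camera adjusted p values were 9.78e-05 and 4.35e-07 in that order of lists, and 0.0742 and 0.249 with an estimated correlation. Counting the heterozygote as a control left 3 and 2 members higher, Dlx1 and Dlx2 among them, and the spread covariate 2 and 3. Of the olfactory bulb list 2 members were higher without wild type 2 and 3 without null 1, and of the GABA list 3 without wild type 3 or null 2. The heterozygote read 11.17 on Gad1 against a null mean of 11.33, and 9.15 on Th against 8.51. Th lost its call without any 1 of the wild type arrays (0.0638, 0.0971 and 0.159) or null 1 (0.0955) or 2 (0.0588), Gabrg3 without wild type 2 (0.0590), wild type 3 (0.0719) or null 2 (0.0623), and Calb2 without wild type 2 (0.0505).

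Of the axon guidance genes that passed, most rose. Of 50 measured ligands and receptors, 9 rose, 1 fell and 40 did not pass, with 14 higher and 1 lower adjusted over the list alone. Unc5d and Plxnd1, named with the largest changes, led the rises and the single fall. Sema3c, a secreted semaphorin gene, rose 4.90-fold, from 6.32 ± 0.34 (SD, n = 3) to 8.61 ± 0.61 (SD, n = 4), and Nrp1, a class 3 semaphorin co-receptor gene, rose 4.19-fold. Dcc and Epha5, named after their values were seen, rose 3.01-fold and 2.85-fold, with the heterozygote at 9.19 and 8.49 near null means of 9.54 and 8.66. The camera adjusted p was 1.77e-05, and 0.0742 with an estimated correlation. With the heterozygote among the controls 4 members were higher and 1 lower, with the spread covariate 7 and 1. Dcc (0.107) and Epha5 (0.156) were not called in the former.

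Cadherin family and glutamate receptor genes rose in part, and on some of them the heterozygote resembled the null arrays. Of 23 cadherin family genes 6 rose and 0 fell (8 and 0 adjusted over the list alone), among them Pcdh17 3.89-fold, Cdh4 2.38-fold, Cdh10 2.38-fold and Pcdh9 2.18-fold. Of 20 glutamate receptor genes 3 rose and 0 fell (5 and 0), namely Grin3a 2.66-fold, Grm3 1.89-fold and Gria1 1.79-fold, while Grik1 differed by 1.03 (adjusted p = 0.0992). Pcdh17 read 9.51 in the heterozygote against 7.20 ± 0.15 (SD, n = 3) in wild type and 9.16 ± 0.31 (SD, n = 4) in null striatum, and Grm3 read 10.76 against 9.56 ± 0.11 (SD, n = 3) and 10.48 ± 0.15 (SD, n = 4). The camera adjusted p values were 0.0245 for the cadherin families and 0.0013 for the glutamate receptors, and 0.280 and 0.0986 with an estimated correlation. The median of the cadherin list was -0.05 although its mean was 0.32. With the heterozygote among the controls 0 members of either list were called, and the cadherin list, whose call was also lost without null 4 (0.0950), had an adjusted p of 0.0694. With the spread covariate 2 cadherin genes were higher and 1 lower, and 1 glutamate receptor gene was higher. Cadherin counts were 3 higher without wild type 2 or null 1 and 1 without wild type 3 or null 2, and glutamate receptor counts 1 without wild type 3 or null 1, 2 or 3 and 5 without null 4. With single arrays left out, Cdh4 reached 0.0863 (lost without wild type 3 or null 2), Cdh10 0.0719 (wild type 2, wild type 3 or null 2), Grin3a 0.108 (wild type 3 or null 1, 2 or 3), Pcdh9 0.110 and Gria1 0.108 (each wild type 2 or 3 or null 1, 2 or 3), while Grik1 was called without null 4 (0.0288).

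Lists for progenitors, apoptosis, stress, microglia and chromatin complexes passed the camera test on few called members. Among 23 neural progenitor genes Prom1, Msi2, Rbpj and Sox2 rose 2.48-fold, 2.37-fold, 1.94-fold and 1.61-fold and 0 fell. Among 19 apoptosis genes 3 rose and 0 fell: Bcl2l11, the pro-apoptotic protein Bim, 4.92-fold, Cdkn1a, the cell cycle inhibitor p21, 2.51-fold, and Xiap, an inhibitor of caspases, 2.05-fold. Among 20 immediate early and stress genes the 2 that rose were the heat shock genes Hspa1b and Hspa1a, 5.25-fold and 3.04-fold. Of 18 microglia and macrophage genes the complement gene C1qa, named after its values were seen, alone rose (1.55-fold, adjusted p = 0.0495; not called without any 1 wild type array or null 1 or 2), with Csf1r at 0.67 (adjusted p = 0.115) and Tyrobp at 0.66 (adjusted p = 0.118), and of 30 NuRD and BAF complex genes Chd5 and Smarca2 rose 2.07-fold and 1.78-fold. Adjusted over the list alone, 6, 3, 4, 5 and 5 members were higher and 2, 0, 1, 0 and 0 lower, in that order. Camera adjusted p values were 0.0245, 0.0245, 0.0288, 0.0245 and 0.0254, and 0.280, 0.249, 0.280, 0.280 and 0.467 with an estimated correlation. Calls of lists were lost for apoptosis without null 4 (0.0548), stress without wild type 1 (0.0598) or null 1 (0.0574), microglia without wild type 1 (0.140) or null 4 (0.101) and the chromatin complexes without wild type 2 (0.0591) or null 3 (0.0503). Among the genes, Prom1 lost its call without wild type 3 (0.0531), Chd5 without wild type 2 (0.0533), and Rbpj, Sox2, Xiap and Smarca2 without wild type 2 or 3 or null 1, 2 or 3, at up to 0.179, 0.150, 0.147 and 0.101, while Tyrobp was called without null 3 (0.0433). With the heterozygote among the controls, 1 progenitor, 2 apoptosis and 2 stress genes were called, and 0 of the microglia and chromatin lists, with the same counts under the spread covariate. Progenitor genes called higher were 2 without wild type 2 or any 1 of null 1 to 3, and 1 without wild type 3, with 1 lower without null 3. Stress genes called were 6 higher and 1 lower without null 4, and chromatin genes 4 without wild type 1, 5 without null 4, 0 without wild type 2 and 1 without any other array.

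Lists that divide the striatum into pathways and compartments did not pass as groups. Of 11 direct pathway (D1-type) genes 1 rose, Zfp521, and 1 fell, Drd1, with Gnb4 short of the threshold (adjusted p = 0.0518), and of 11 indirect pathway (D2-type) genes Gpr6 fell and 0 rose, with Plxdc1 at -0.31 (adjusted p = 0.295). Of 16 striosome (patch) genes 4 rose and 1 fell: Kcnip1 rose 2.76-fold, Nnat 2.11-fold and Bach2 1.82-fold, while Reln, the extracellular glycoprotein reelin, fell 2.97-fold, from 10.78 ± 0.31 (SD, n = 3) to 9.21 ± 0.40 (SD, n = 4). Oprm1, the mu opioid receptor and patch marker, chosen after its values were seen, differed by 0.07 (adjusted p = 0.852). Of 13 matrix genes Efnb3 and Id4 rose 2.72-fold and 2.43-fold while Brinp3 and Rasgrp2 fell 2.26-fold and 2.23-fold, and Calb1, the matrix marker calbindin, also chosen after its values were seen, differed by 0.04 (adjusted p = 0.920). Adjusted over the list alone, 4, 0, 6 and 4 members were higher and 6, 1, 1 and 3 lower. Camera adjusted p values were 0.723, 0.211, 0.0598 and 0.502, and the patch list was called without wild type 2 (0.0432), without null 2 (0.0356) and with array weights (0.0412). The heterozygote read 10.39 on Bach2, above the null mean of 9.68, and 11.15 on Reln, with the wild type arrays; with it among the controls Reln was the 1 patch gene called, 0 pathway genes were, and Id4 (0.0584) was not. The fall of Reln rested on 1 of its 2 probe sets, the other not falling. Of the patch genes 1 was higher without wild type 2 or 3 or null 2 or with the spread covariate, and 2 without null 1 or 3. Left-out arrays ended the calls of Kcnip1 (wild type 2 or 3 or null 1, 2 or 3, up to 0.0744), Bach2 (wild type 2 or 3 or null 2, up to 0.0840) and Brinp3 (wild type 2 or 3 or null 1 or 2, up to 0.111), while Gnb4 was called without null 3 (0.0343).

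Single members stood out on further lists that did not pass camera. Of 29 neuropeptide and receptor genes Nts and Pnoc, the precursor of nociceptin, rose, Pnoc 3.40-fold, and 0 fell. The mean of this list was 0.08 while its median was -0.10 and camera pointed down. Of 20 interneuron genes Calb2 and Lhx6 rose, Lhx6 2.09-fold, with Maf at 1.66 (adjusted p = 0.0547) and a list mean of 0.27 against a median of -0.02, and Lhx6 was also the 1 member that rose of 13 septal and medial ganglionic eminence genes, with Lhx8 at 1.34 (adjusted p = 0.111), a mean of 0.13 and a median of -0.08. Of 18 retinoic acid genes Rdh10 rose 2.44-fold and Crabp1, a cytoplasmic retinoic acid carrier, fell 2.12-fold, from 10.62 ± 0.02 (SD, n = 3) to 9.54 ± 0.09 (SD, n = 4). Of 18 growth factor and receptor genes Gfra1 rose 2.91-fold and Fgf14 2.23-fold, of 43 potassium and calcium channel genes Kcnd3 rose 2.89-fold, Kcna5 2.81-fold and Cacna2d2 1.93-fold on 1 of its 3 probe sets, the others not rising, and 0 fell on either list. Without null 4 there were 5 higher channel genes and 1 lower. The camera adjusted p values were 0.812, 0.203, 0.704, 0.199, 0.159 and 0.163, and adjusted over the list alone 2, 5, 3, 2, 4 and 8 members were higher and 0, 1, 0, 2, 0 and 1 lower. Fry, which makes no comparison with other genes, called the retinoic acid (adjusted p = 0.0096), growth factor (0.0430) and channel (0.0304) lists. Lhx6 lost its call without any 1 array except null 4 (up to 0.147), Rdh10 without wild type 2 or 3 or null 1 or 3 (up to 0.108), Gfra1 without wild type 2 or 3 (up to 0.0618), Kcna5 without wild type 2 (0.0548) and Cacna2d2 without wild type 3 (0.0598). The heterozygote among the controls ended the calls of Kcnd3 (0.0921), Fgf14 (0.292), Kcna5 (0.258), Cacna2d2 (0.190), Rdh10 (0.253) and Lhx6 (0.314), leaving 0 channel genes. The spread covariate ended those of Pnoc (0.0853), Gfra1 (0.101), Calb2 (0.0988), Kcna5 (0.103), Cacna2d2 (0.0653), Rdh10 (0.220) and Lhx6 (0.259). Calls were gained by Maf without wild type 1 (0.0457) or null 4 (0.0230), Lhx8 without wild type 2 (0.0297), and, without wild type 2, the interneuron (0.0167) and growth factor (0.0432) lists.

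Markers of other tissues and cell types gave few calls. No gene passed among 19 cortical glutamatergic, 27 cell cycle, 16 oligodendrocyte, 19 endothelial and mural, 15 meningeal and fibroblast, 9 erythroid, 12 choroid plexus and ependymal, 20 cholesterol synthesis or 4 sex-linked genes, either over all genes or adjusted over the list alone. On 3 of these lists the members of widest difference were Tle4 at 0.86 (adjusted p = 0.109) among the cortical genes, Mcm6 at 0.63 (adjusted p = 0.137) in the cell cycle and Insig1 at 0.89 (adjusted p = 0.143) in cholesterol synthesis. Camera adjusted p values for these lists were, in that order, 0.714, 0.704, 0.351, 0.0598, 0.379, 0.341, 0.304, 0.0947 and 0.848. Lists were called as higher for endothelial and mural genes without wild type 2 (0.0217), wild type 3 (0.0439), null 1 (0.0450) or null 2 (0.0168) and for cholesterol synthesis without null 4 (6.77e-04), and as lower for the choroid plexus without null 2 (0.0239). Mcm6 was called without null 4 (0.0267) and Insig1 without wild type 1 (0.0074). Xist, expressed from the inactive X chromosome, read 9.63 and 10.09 in wild type 1 and 2 and 10.64 in null 3, and from 5.97 to 6.82 in the other arrays, while Eif2s3y of the Y chromosome read 2.98, 3.10 and 2.76 in those 3 arrays and from 6.22 to 7.90 in the others. Sex is not given in the sources used here, but by both transcripts wild type 1 and 2 and null 3 read as female and the other arrays as male. The wild type and null groups were thus unbalanced in sex. With the Xist value as a covariate, chosen after seeing the data, 808 genes were higher and 193 lower. Of 18 astrocyte genes 2 rose (2 adjusted over the list alone), the glutamine synthetase gene Glul 1.89-fold and the glutamate transporter gene Slc1a2 1.72-fold, and of 11 housekeeping genes 1 rose (3 adjusted over the list alone), Gusb 2.35-fold on 1 of its 2 probe sets, the other not rising, with camera adjusted p values of 0.457 and 0.0598. The housekeeping list was called without wild type 1 (0.0437) or null 2 (0.0455). Slc1a2 and Glul lost their calls with single arrays left out, Slc1a2 without wild type 2 or 3 or null 1, 2 or 3 (up to 0.157) and Glul without wild type 2 or 3 or null 2 (up to 0.0841). The heterozygote among the controls ended the calls of Glul (0.262), Slc1a2 (0.569) and Gusb (0.110), leaving 0 on both lists, and the spread covariate those of Glul (0.0848) and Slc1a2 (0.186). Ttr, the main choroid plexus transcript, ranged 80.4-fold over the 8 arrays, with 13.34, 9.38 and 11.44 in wild type 1 to 3, 7.44 in the heterozygote and 7.11, 13.44, 8.27 and 11.17 in null 1 to 4.

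**Figure D3:**
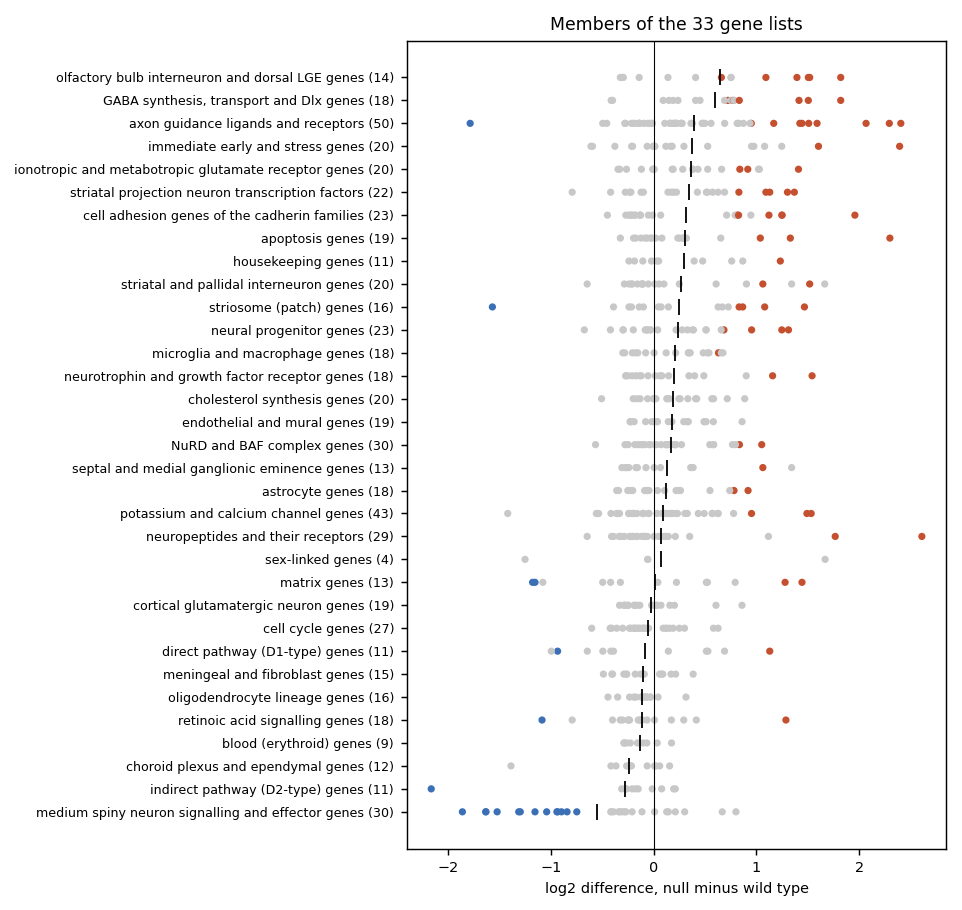
Log2 difference, null minus wild type, of each measured member (points) of the 33 gene lists, with the number of measured members in brackets; red points rose and blue points fell at a limma adjusted p under 0.05, grey points did not pass, and black ticks are list means. Blue points gather on the medium spiny neuron signalling list, with 13 of 30 members. Red points are spread over several lists, among them olfactory bulb (6 of 14), GABA (6 of 18), cadherin (6 of 23) and axon guidance (9 of 50).

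The heterozygote array had no replicate and was placed between the group means without a test, 0 being the wild type mean and 1 the null mean. On the 521 genes higher in null striatum its median position was 0.83, past the midpoint on 433 of them (83.1%). On the 143 lower genes its median position was 0.12, past the midpoint on 26 (18.2%). Simulated wild type arrays placed the same way gave medians of 0.08 and 0.17, with noise independent between genes and no array-wide difference. Among the lower genes Nexn, Thy1, Kcnip2 and Ngef read 9.92, 9.44, 9.75 and 10.80 in the heterozygote, beside wild type means of 9.86, 9.36, 9.47 and 10.82. Others lay further from the wild type mean on either side, with quartiles of position at -0.08 and 0.43, Drd1 at -0.96 and Rasl11b at 0.37. A wild type array left out of the comparison and placed in the same way had a median position of 0.53 for wild type 1, -0.02 for wild type 2 and 0.02 for wild type 3 on the genes then called higher, and 0.52, 0.11 and 0.29 on those called lower. Wild type 1 also set the result for lower genes: without it 253 genes were lower and the heterozygote's median position on them was 0.72.

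**Figure D4:**
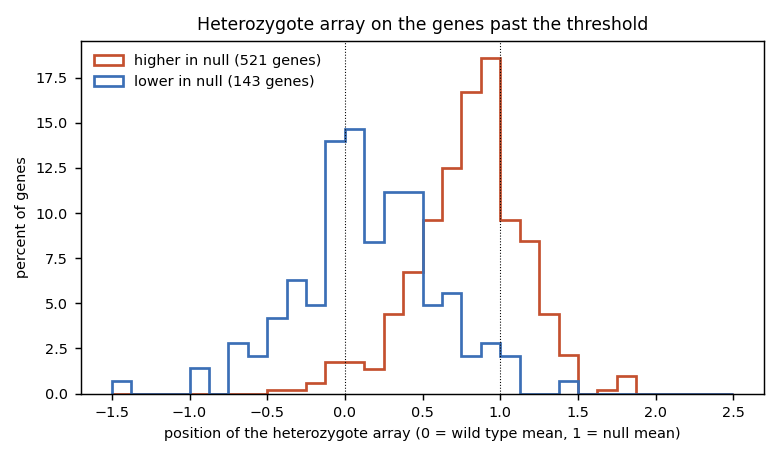
Position of the heterozygote array on each called gene, with 0 at the wild type mean and 1 at the null mean, as the percent of the 521 genes higher (red) and 143 genes lower (blue) in null striatum; values beyond the axis are drawn in the end bins. The higher genes centre on 0.83 and the lower genes on 0.12.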

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

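Each named gene and list mean was tested for 1 array lying apart from the other 3 of the null group, by Dixon's ratio at the 0.05 level. Of 158 results tested 10 passed, where chance gives 7.9, since chance alone passes about 1 in 20 groups. Plagl1 read 11.06 in null 3, with the nearest null array at 9.96. Nefm read 8.49 in null 4, with the nearest at 9.33. Rasl11b read 6.64 in null 4, with the nearest at 7.18. Arhgdib read 7.51 in null 4, with the nearest at 7.19. Rbpj read 7.81 in null 4, with the nearest at 8.61. Gria1 read 10.38 in null 3, with the nearest at 10.02. Eif2s3y, a gene of the Y chromosome, read 2.76 in null 3, with the nearest at 6.60. Xist, expressed from the inactive X chromosome, read 10.64 in null 3, with the nearest at 6.82. These Eif2s3y and Xist values form a female pattern, which null 3 shared with wild type 1 and 2. The Bcl11b probe set with the largest fall read 9.24 in null 3, with the nearest at 8.33. The mean of the apoptosis list was 8.05 in null 3, with the nearest at 7.92.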

How the results depend on the processing

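The spread covariate, the Xist covariate and the omission of the arrays of highest Ttr were tests chosen after the result was seen. Counts of calls moved with most settings, and the cause was not tested unless the setting itself changes the threshold. Of probe sets, 840 were higher and 204 lower. With arrays centred on their median the counts were 548 and 124, with array weights 2686 and 965, with the heterozygote among the controls 110 and 96, with a fold change of at least 2 added to the threshold 512 and 78, and with a threshold of 0.10 they were 1690 and 449. Quantile normalization gave 328 lower probe sets and 277 lower genes. SAM scores beyond 2 in either direction gave 4630 higher and 5717 lower probe sets and 2026 higher and 2341 lower genes, with an estimated false discovery rate of 21.7%. The signal spread covariate gave 189 and 93, the Xist covariate 1562 and 319, and omission of wild type 1 and null 2, the arrays of highest Ttr, 412 and 62.

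For genes, against 521 higher and 143 lower, the counts were 327 and 78 with centred arrays, 1406 and 543 with array weights, 74 and 78 with the heterozygote among the controls, 290 and 52 with the fold change threshold and 979 and 310 at a threshold of 0.10. The spread covariate gave 133 and 81, the Xist covariate 808 higher and the omission of both Ttr arrays 291 and 49. Leaving out each array in turn gave 210 to 1733 higher and 76 to 443 lower probe sets, and 150 to 1030 higher and 58 to 253 lower genes.

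With the replicate number as a block, 1696 probe sets and 1003 genes were higher. Deviations of wild type and null arrays of the same number correlated at -0.25, -0.31 and -0.17, and those of different numbers at -0.42 to 0.37. The numbers thus showed no sign of pairing animals, though these correlations cannot exclude it. In the block fit the adjusted p was 0.141 for microglia, 0.0546 for the cadherin families and 0.0553 for apoptosis, and cholesterol synthesis was called (4.72e-04).

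Bcl11b differed by -1.01 without the pair of Ttr arrays (p adjusted over genes 0.0571, against 0.0069 in the main fit). The median position of the heterozygote on lower genes ranged from 0.12 to 0.72 with 1 wild type array left out, the highest value without wild type 1.

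With an estimated correlation camera called 0 of the 33 lists, against 12 with the preset one. Adjusted p values were 0.0742 for the striatal transcription factors, the olfactory bulb list and axon guidance, 0.0986 for medium spiny neuron signalling and the glutamate receptors, 0.249 for GABA and Dlx genes and apoptosis, 0.280 for neural progenitors, microglia, stress genes and the cadherin families, and 0.467 for NuRD and BAF complexes. Neural progenitors had 0.171 with dim probe sets left out and 0.0525 without the Ttr arrays. Microglia had 0.0643 by fry, 0.0556 with array weights, 0.0944 with the Xist covariate and 0.135 without the Ttr arrays, and 0.0023 to 0.140 with 1 array left out. Stress genes had 0.0520 by fry, 0.234 with dim probe sets left out, 0.0974 with the heterozygote among the controls, 0.0698 with the spread covariate and 0.0525 without the Ttr arrays, and 0.0111 to 0.0598 with 1 array left out. The cadherin families had 0.143 with dim probe sets left out, 0.0694 with the heterozygote among the controls, 0.0602 with the spread covariate and 0.0153 to 0.0950 with 1 array left out. NuRD and BAF complexes had 0.201 by fry, 0.239 with dim probe sets left out, 0.438 with quantile normalization, 0.0694 with the heterozygote among the controls, 0.451 with the spread covariate and 0.0062 to 0.0591 with 1 array left out. Apoptosis had 0.123 with dim probe sets left out, 0.0537 with quantile normalization and 0.0162 to 0.0548 with 1 array left out. Cholesterol synthesis, not called as it stood, was called as lower with the spread covariate (0.0145) and as higher with array weights (0.0414), the Xist covariate (0.0413) and without null 4 (6.77e-04).

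Other lists gained calls. Fry called the retinoic acid (0.0096), channel (0.0304) and growth factor (0.0430) lists. Array weights called the patch (0.0412) and housekeeping (0.0428) lists, and the spread covariate called the interneuron (0.0175), cell cycle (0.0461, lower), endothelial (0.0230) and growth factor (0.0258) lists. The Xist covariate called the endothelial (0.0411) and housekeeping (0.0411) lists, which were also called with the mean of each gene's probe sets (endothelial, 0.0428) and without the Ttr arrays (housekeeping, 0.0374). The growth factor list was called with dim probe sets left out (0.0487). No named gene past the threshold changed sign in any setting; Penk, Oprm1, Foxp1 and Calb1, which did not pass, changed sign in some, such as Penk at -0.21 with the heterozygote among the controls and Calb1 at -0.20 without null 3.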

Other observations

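The tests chosen only after the result was seen were those on the position of the heterozygote, on wild type 1 and on Ttr against genotype, with the spread and Xist covariates and the omission of the arrays of highest Ttr, and the imprinted list was written after some of its genes had been noticed. Ptk2b, Nectin3 and Tgfa were also chosen after their values were seen. Ptk2b, a calcium-dependent tyrosine kinase, Nectin3, an adhesion protein, and Tgfa, an epidermal growth factor receptor ligand, were 3.01-fold, 3.42-fold and 2.56-fold lower in null striatum. On these genes the heterozygote stood at 0.18, 0.11 and -0.07 of the distance from wild type to null, unlike its place on most of the higher genes. It also stood near wild type on some of the 12 largest rises. Its position was -0.13 on Bnc2, 0.12 on Fign and Dlk1, 0.10 on Nts and 0.01 on Unc5d, while it lay past the midpoint on 4 of the 12. Ptk2b, Nectin3 and Tgfa, with Itpka, Nexn, Ngef, Bnc2, Fign, Dlk1, Nts and Unc5d, would be the first to measure by another method in more animals. This choice favours genes on which the heterozygote read near wild type.

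All 35 splits of the 7 arrays into 4 and 3 were counted. The real split gave 840 higher probe sets and 521 higher genes against 15 and 9 in the highest other split. Thus 1 of 35 splits reached these counts, the lowest share that these splits can give. Signal spread also differed between the groups, so this count cannot tell genotype from an array-wide difference. For lower probe sets and genes the real split gave 204 and 143, the highest other split 392 and 240, and 2 of 35 reached them. That split set null 1 to 3 against the wild type arrays and null 4, so its lower calls were higher in null 1 to 3. Turned to that side, its 392 and 240 stand beside the real 840 and 521, and its 15 and 9 beside 204 and 143. For lists the real split gave 12 and the highest other, wild type and null 2 against the other null arrays, 13, and 2 of 35 reached 12. Both splits keep most of the genotype contrast and are not free of it, so as counted they neither exclude chance for the lower counts and the lists nor are evidence for it. Splits with 2 wild type and 2 null arrays in the group of 4 hold little of that contrast and still gave 1 to 5 lists. Camera at the preset correlation thus called lists with little difference of genotype. By exact permutation of list means over the splits, the lowest p was 0.0286, and 0.0673 adjusted over the lists. The former is the lowest p that 35 splits can give. Many lists reached it, among them medium spiny neuron signalling and the neuropeptides, which camera did not call. This permutation had little room to pass after adjustment, so it is no evidence that the lists do not differ.

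The excess of higher calls could come from the loss of Bcl11b, from an array-wide difference in signal spread, or from both. With the SD of each array as a covariate 67.0% of called probe sets were higher, between the bounds set before that fit was run. Loss of Bcl11b and signal spread thus cannot be told apart for these probe sets. Quantile normalization, which makes the spread of all arrays equal, gave 839 higher and 328 lower probe sets, 71.9% of them higher. Of the 521 higher genes 455 kept their call with quantile normalization, but 133 with the spread covariate. Quantile normalization thus left most higher calls, and more lower calls made their excess smaller, while the covariate removed most higher calls. Spread and genotype overlap in these arrays, so that loss does not decide between them. The heterozygote, with Bcl11b at the wild type level, had a median position 0.714 further toward null on higher than on lower genes, and wild type 1, the wild type array of widest spread, lay 0.511 further toward null than the other wild type arrays on higher genes, so part of the shift may arise without genotype; on lower genes wild type 1 also lay toward null (0.52, against 0.11 and 0.29), so its shift was not confined to higher genes. An effect of 1 lost allele stays open and untested with a single heterozygote, and the position on lower genes was 0.72 without wild type 1. More heterozygotes, or the raw array files normalized together, would separate these explanations.

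Ttr differed widely between arrays, and choroid plexus tissue in some punches is a candidate source. Ttr followed the mean of the other 11 choroid plexus genes over the 8 arrays (r = 0.861, rho = 0.833, exact permutation p = 0.0081 and 0.0154, r = 0.845 without the 2 arrays farthest from the median, 1 correlation tested). Single members followed it unevenly, 6 of 11 with r over 0.7 and Kl with 0.04, and none of them ranged over more than 1.64 on the log2 scale against 6.33 for Ttr. Ttr was higher in wild type in 0.667 of the 12 wild type and null pairs, and both the lowest (7.11) and the highest (13.44) array were null, so genotype alone does not account for the range, while a difference by genotype beside it stays open (-1.39, 95% interval -4.48 to 1.70). Sections at the level of the punches, stained for Ttr, would test this.

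The imprinted genes Dlk1, Plagl1 and Asb4 stood among the largest rises, and these with Nnat and Meg3 were set aside. The other 33 measured were higher as a group (camera p = 1.26e-04, but 0.0742 with an estimated correlation). Shared regulation of imprinted genes is a possible explanation that was not tested. With the heterozygote among the controls the group kept its camera p (1.23e-04), while of single genes only Dlk1 was called. Of the 33, Peg3, Usp29 and Mest were called, but lost their calls in 4, 3 and 6 of 7 fits without 1 array (up to 0.0867, 0.0925 and 0.130) and with the spread covariate (0.160, 0.104 and 0.169), and the other probe set of Usp29 differed the other way. Flanking DNA of another strain could act on Dlk1, near Bcl11b: of the 100 nearest genes 2 were called, Dlk1 and Amn, a ratio of 0.547 to the share elsewhere with an upper limit of 2.16, so flanking DNA and its absence cannot be told apart.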
